A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

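Cyclobutane pyrimidine dimers, the UV lesions that join adjacent pyrimidines on a DNA strand, were mapped by CPD-seq in 9 libraries of naked genomic DNA from the budding yeast strain BY4741. Per the labels, DNA was purified, incubated with or without the CpG methyltransferase M.SssI, irradiated with 500 J/m2 of UVB or 90 J/m2 of UVC, cut at dimers with T4 endonuclease V, ligated to a barcoded adaptor and amplified by PCR. The labels give 2 UVB experiments, each with a methylated, an unmethylated and an unirradiated library, and 1 UVC experiment with the same 3 libraries. Samples were grouped by these labels into UVB methylated (2 libraries), UVB unmethylated (2), UVC methylated (1), UVC unmethylated (1) and unirradiated (3). The methylation reaction of UVB replicate 1 used less enzyme per amount of DNA and a shorter incubation than those of UVB replicate 2 and UVC, per the labels. Nothing in the labels says that replicates came from separate cultures, and p-values therefore measure only the spread between these samples.

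Per the submitters' processing notes, reads were mapped to the yeast genome build sacCer3, and Bowtie2 version 2.2.6, SAMtools and bedtools were used. The role of each tool, any handling of duplicate reads and the version of the other tools are not given in the sources used here. Each sample has 2 deposited files. The first deposited file holds counts of lesion reads at each of the 16 dinucleotides, not normalized. The other deposited file lists 1 line per read at a dipyrimidine with its position and strand, and a score, the mapping quality of that read. Reads per position, context and gene were counted from these lines. The 4 dipyrimidine counts of each dinucleotide file sum to the number of lines in the position file of the same sample. Reads carry no molecular identifier and came through PCR, so intervals cover counting error only.

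The barcode differed with methylation. Both UVB methylated libraries carried adaptor A3 and both unmethylated ones A2, while UVC used A6 and A5. Read names showed 2 sequencing runs, 1 for all libraries of UVB replicate 1 and the other for UVB replicate 2 and UVC. Of the dipyrimidine reads, 74.3% and 73.9% in the UVB methylated and unmethylated libraries of the first run had a mapping quality of at least 10, against 85.9% to 87.1% of those in the irradiated libraries of the second run. Barcode and methylation cannot be told apart within UVB, nor wavelength and experiment.

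No genome sequence was used here, so TCG, CCG, tetranucleotide and hexanucleotide contexts planned before the data were examined were not analysed here. Purine (R) and pyrimidine (Y) sequence was instead inferred from which positions are listed as dipyrimidines on either strand. This determined 98.1% of 12156428 spanned bases with 0 conflicts. Tested on simulated data, the same steps determined 97.0% of bases and got 0.0753% of these wrong. Each dipyrimidine was assigned to 1 of 64 contexts by 3 bases on each side and to 1 of 1024 contexts by 5 bases on each side, written 5′ to 3′ on the lesion strand. In YYY-YY-YRY, for example, the central YY is the dipyrimidine. Of nuclear dipyrimidine reads, 95.2% to 95.9% had a context. Every CpG whose cytosine is the 3′ base of a dipyrimidine lies at a dipyrimidine followed by a purine, but T and C, or A and G, are not separated. This substitution, the dinucleotide test, the test of single sites of any sequence and the interaction over single sites were chosen after seeing the data.

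Counts were compared with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling) in R 4.3.3, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. Contexts used nuclear reads. Genes used reads on both strands over 6477 nuclear genes matched to the annotation, of which 6427 passed filterByExpr. Single sites needed at least 100 reads over the 4 UVB libraries, which left 9402, with library sizes from the context fit. Of these, 8632 lie in the rDNA, taken as chromosome XII 451786 to 489469. The interaction (methylated minus unmethylated in UVC, minus the same in UVB) and the wavelength comparison used the 6 irradiated libraries, with the lone UVC libraries assumed to vary like the UVB ones. Of 15 gene lists fixed before the data were examined, 11 were tested with camera and fry from limma 3.58.1, and 4 were not analysed here because their genes or their CpG content were not in the tables used. Dipyrimidine shares of irradiated and unirradiated libraries were compared with an exact two-sided permutation test over 84 splits. Shares of single libraries have Wilson 95% intervals from scipy 1.17.1, under Python 3.11.15, and plots used matplotlib 3.10.9.

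Named contexts were the 5 highest and 5 lowest log2 fold changes past the threshold that moved the same way in both experiments, for each set of contexts. Named genes were to be the 10 highest and 10 lowest by the same rule, and named sites the 5 highest and 5 lowest. The wavelength comparison names the 5 highest and 5 lowest contexts past its threshold. Items named outside these rules are marked as chosen after their values were seen.

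Alternatives were the replicate number as a block, leaving out each library in turn, library size in place of TMM, DESeq2 1.42.0, and subtraction of the unirradiated library of the same experiment scaled by reads outside dipyrimidines. Others were other count minimums, inclusion of the mitochondrial genome, removal of the rDNA, removal of the 6346 positions with the highest counts, and other denominators for the dipyrimidine shares. A mapping quality minimum of 10 and fits within a sequencing run were chosen after seeing the data. The labels give each replicate number its own methylation reaction conditions, and the numbers therefore pair the samples. Deviations from the group mean of libraries with the same number correlated at 0.48 over the 64 contexts, 0.50 over the 1024 and 0.39 over genes. Replicates were not copies of each other, with a chi-square per degree of freedom over the 1024 contexts of 67.3 for the UVB methylated pair and 74.6 for the unmethylated pair.

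Each test was tested on simulated data with changes of known size. At log2 changes of 0.2 and 0.4, it recovered 33.3% and 83.3% of changed contexts among the 64, 7% and 73% among the 1024, and 41.8% and 92.5% of genes. At changes of 1 and 2 it recovered 16% and 85% of single sites, and 0% and 6% in the interaction over sites. For the interaction over the 64 contexts and the 16 dinucleotides, recovery was 0% at both sizes, so a count of 0 there says little. The wavelength comparison recovered 66.7% and 83.3%. In the gene simulation 15 of 6227 unchanged genes were called. It changed 67 genes at 0.2, 67 at 0.4 and 66 at 1, and recovered 98.5% of the last. Its recovery holds for that many changed genes and need not hold where few change.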

Results

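Dimer positions were read in 9 libraries of naked BY4741 yeast DNA. The 4 UVB libraries held 21030756 and 14300740 dipyrimidine reads with CpG methylation (replicates 1 and 2) and 21367356 and 11941615 without it. The UVC libraries held 7635173 reads with and 10034575 without methylation, and the 3 unirradiated libraries held 1251408, 1057813 and 1831049. Over the 4 UVB libraries together, a nuclear dipyrimidine position had a median of 8 reads. Reads over genes that BY4741 lacks were scarce, with 32.0 per kb over LEU2, 6.22 over URA3 and 2.25 over MET17, against a median of 6855 per kb over protein-coding genes. HIS3, which this strain lacks in part, had 3890 reads per kb.

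The first comparison asked whether reads marked UV damage. Lesion reads of irradiated libraries fell mainly at dipyrimidines, where pyrimidine dimers form, at 78.7% ± 2.10 (SD, n = 6) of mapped lesion reads. Unirradiated libraries had 24.8% ± 0.434 (SD, n = 3). Irradiated libraries ranged from 75.8% to 81.1%, all above the unirradiated range of 24.3% to 25.2%. The difference of 53.9 percentage points gave p = 0.0238 in an exact two-sided permutation test, the smallest p that 84 splits allow. Counting error was small beside this, with Wilson 95% intervals of at most 0.0411 points on either side. The difference was 51.8 points within the first sequencing run and 54.9 within the second.

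**Figure D1:**
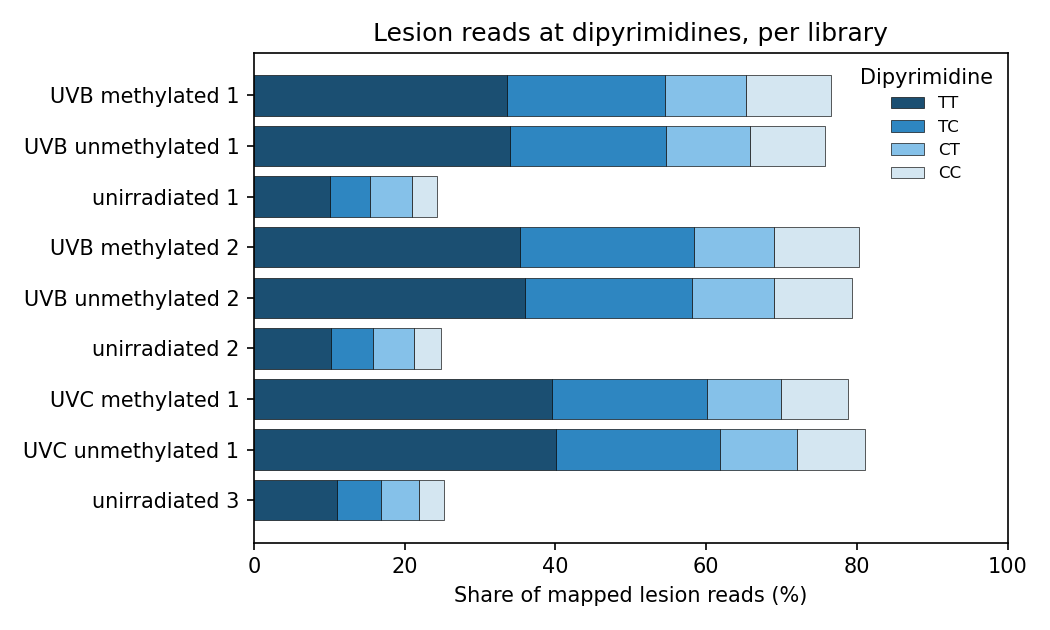
Share of mapped lesion reads (percent, horizontal axis) at TT, TC, CT and CC in each of the 9 libraries, stacked. The 6 irradiated libraries reach 75.8% to 81.1%, and the 3 unirradiated ones 24.3% to 25.2%.

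Which dipyrimidines carried the reads was compared between methylated and unmethylated DNA. CC, the dipyrimidine of 2 cytosines, took 14.6% of dipyrimidine reads with methylation and 13.2% without in UVB replicate 1, and 14.1% against 13.0% in replicate 2. Its mean log2 ratio over both UVB pairs was 0.13 ± 0.02 (SD, n = 2). TC, the other dipyrimidine that ends in cytosine, had log2 ratios of 0.01 and 0.04 in the UVB pairs and -0.05 in UVC. CT had -0.06, -0.05 and -0.01, and TT had -0.03, -0.05 and 0.02. As a share of all lesion reads, TT was lower with methylation in UVC and in both UVB pairs. In UVC, CC took 11.3% of reads with and 11.1% without methylation, a log2 ratio of 0.02 with a 95% counting interval of 0.0164 to 0.0241, and this sign turned to -0.02 over all lesion reads and -0.0031 over TT reads. Across the 16 dinucleotides, edgeR called 0, with 0 at an unadjusted p under 0.05, while DESeq2 called 1 lower. With the replicate number as a block, 2 passed, CC with adjusted p = 0.0229 and AC with adjusted p = 0.0253, both higher in methylated DNA.

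Bases around the dimer were then compared in UVB. Dipyrimidines behind a run of pyrimidines took a smaller share of reads in methylated DNA, and dipyrimidines flanked by purines a larger one. Isolated dipyrimidines, with a purine on each side, held 17.0% of reads with methylation and 13.9% without in replicate 1, and 17.7% against 15.9% in replicate 2. In UVC they held 18.5% and 18.4%, and in the unirradiated libraries 25.0% to 25.4%. Dipyrimidines behind 3 pyrimidines on the 5′ side had log2 ratios of -0.35 and -0.16 in the UVB pairs and -0.01 in UVC. Counting intervals of these irradiated shares were at most 0.0351 points on either side.

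Of the 64 contexts, 12 passed in edgeR, 2 higher and 10 lower in methylated DNA. YYY-YY-YRY and YYY-YY-YRR fell most, by 0.42 each on the log2 scale (SE 0.12, adjusted p = 0.0207 for both). YYY-YY-YYR fell by 0.36, and YYY-YY-RRR and YYY-YY-RRY fell by 0.28 each. RRR-YY-RYY rose by 0.35 (SE 0.12) and RYR-YY-RYY by 0.18 (SE 0.07), and these 5 contexts each had adjusted p = 0.0414. Without 1 library the value of RRR-YY-RYY lay between 0.12 and 0.62 that of RYR-YY-RYY between 0.11 and 0.26, and those of YYY-YY-RRR and YYY-YY-RRY between -0.14 and -0.44. Every one of the 12 moved the same way in both UVB pairs. With the replicate number as a block 0 of 64 passed in edgeR, with a smallest adjusted p = 0.0842, 13 at an unadjusted p under 0.05 and 21 called by DESeq2 without the block, and 0 passed when any 1 of the 4 libraries was left out (3 to 23 at an unadjusted p under 0.05). Scaled by library size, 11 passed, 9 of them higher and 2 lower, so the direction of the counts depends on the scaling.

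**Figure D2:**
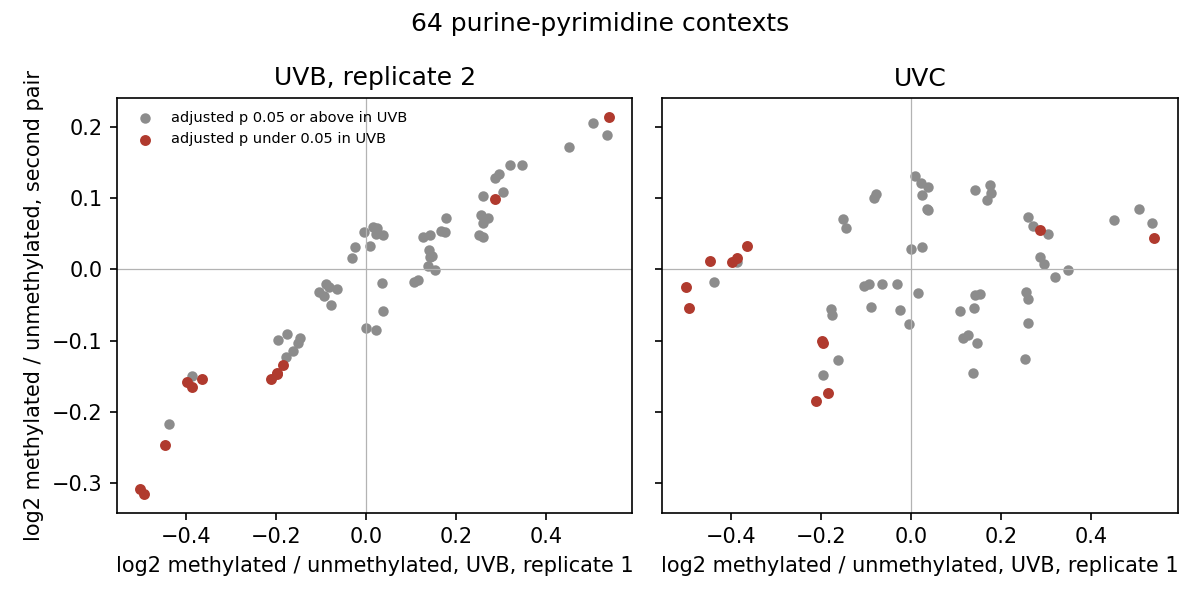
Log2 ratio of methylated to unmethylated reads in the 64 contexts, UVB replicate 1 (horizontal axis) against UVB replicate 2 (left) and UVC (right), red for the 12 contexts past the threshold in UVB. Ratios of the UVB pairs correlate at r = 0.95 across contexts, and those of UVB replicate 1 and UVC at 0.25.

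Of the contexts of 5 bases on each side, 133 passed, 29 higher and 104 lower. Those that fell most were YRYYY-YY-YRYRY (by 0.47, adjusted p = 5.1e-04), YRYYY-YY-YRRRR (by 0.46), YRYYY-YY-YRYYR (by 0.46), YYYYY-YY-YRRYR (by 0.45) and YYYYY-YY-YRRRR (by 0.44). RRRRR-YY-RYYRY rose most, by 0.45 (adjusted p = 0.0344), followed by RRRRR-YY-RYYYY (0.41), YRRRR-YY-RYYYY (0.41), YRRRR-YY-RYYRR (0.39) and RRRRR-YY-RRYRR (0.39). Without 1 library, these 5 risen contexts lay between 0.11 and 0.76, and the 5 that fell most between -0.35 and -0.57. DESeq2 kept 1 of the 5 risen contexts, YRRRR-YY-RYYYY, and all 5 that fell. All 128 contexts with 3 pyrimidines on the 5′ side had negative ratios (median -0.31, 81 past the threshold), and 89.5% of the 256 isolated contexts had positive ones (median 0.21, 25 past it). Without 1 library these medians lay between -0.24 and -0.43 and between 0.09 and 0.30. With the block 226 passed in edgeR, 78 higher and 148 lower, 126 of them among the 133, and scaled by library size 118 passed, 72 higher and 46 lower. The count rested on replicate 1, with 0 contexts passing without its unmethylated library, 1 without its methylated library, 67 without the methylated library of replicate 2 and 262 without the unmethylated one.

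Tested as sets of contexts of 5 bases on each side, camera with its preset correlation gave adjusted p = 4.2e-71 for 3 pyrimidines 5′ and adjusted p = 6.6e-24 for isolated dipyrimidines. It gave adjusted p = 6.2e-22 for a purine against a pyrimidine directly 5′ (medians 0.14 and -0.07) and adjusted p = 2.3e-09 for the same directly 3′ (medians 0.09 and -0.04). Without 1 library, medians lay between 0.07 and 0.19 for a purine directly 5′ and between -0.02 and -0.13 for a pyrimidine there, which was -0.0066 when scaled by library size. A pyrimidine directly 3′ lay between -0.02 and -0.07 without 1 library and turned to 0.03 when scaled by library size. Contexts with only a purine 3′ (median -0.0036, adjusted p = 0.0719) or only a purine 5′ (median 0.08, adjusted p = 0.0745) did not pass, and the former turned to 0.06 by library size and 0.02 without the unmethylated library of replicate 1. The median of the latter lay between 0.02 and 0.11 without 1 library. None of the 8 sets passed with an estimated correlation, where adjusted p = 0.262 for the lowest and 0.621 for the highest, and none passed fry, with adjusted p = 0.268 to 0.491. Contexts within a library are not independent replicates.

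Base by base, the shift lay mostly on the 5′ side of the dimer. A purine directly 5′ raised the methylated over unmethylated ratio by 0.31 in UVB replicate 1 and 0.14 in replicate 2, and gave -0.06 in UVC. At the third base 5′ the values were 0.31, 0.14 and 0.10. Directly 3′ they were 0.16, 0.12 and 0.06, and at bases 2 to 5 on the 3′ side no value exceeded 0.03 in size. Libraries of equal state also differed there, by up to 0.18 between the unmethylated UVB libraries, 0.15 between the methylated ones and 0.19 among unirradiated ones, over the first 5 bases 5′. Directly 3′, the unmethylated UVB libraries differed by -0.14 and the methylated ones by -0.11.

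**Figure D3:**
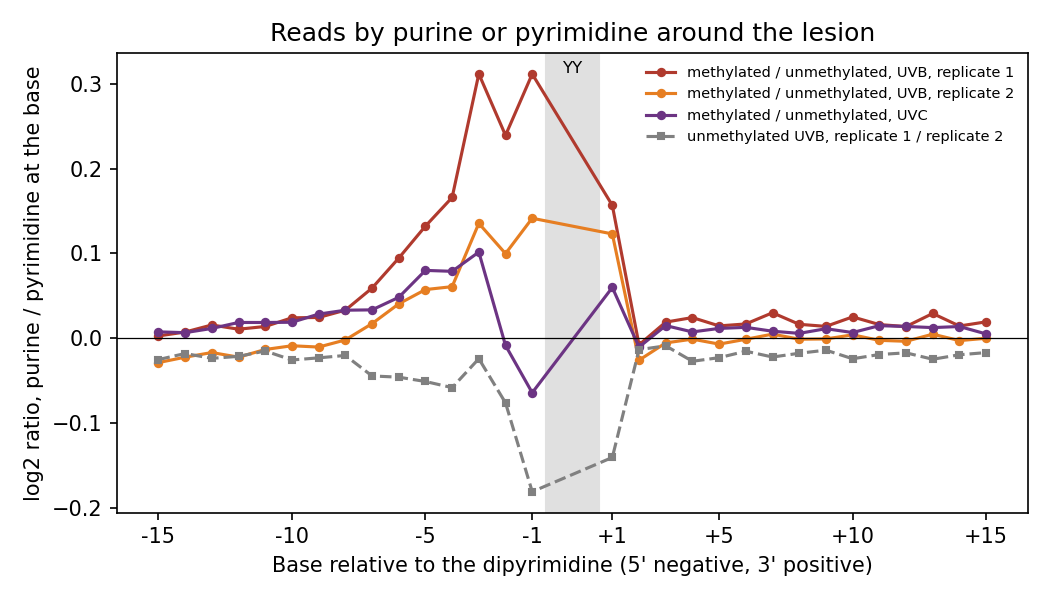
Log2 ratio of reads with a purine to reads with a pyrimidine (vertical axis) at each of 15 bases on either side of the dipyrimidine, for methylated over unmethylated DNA in the 3 pairs and for the unmethylated UVB libraries against each other (dashed). Values at the base directly 5′ are 0.31, 0.14 and -0.06 for UVB replicate 1, UVB replicate 2 and UVC, and -0.18 between the unmethylated UVB libraries.

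Reads summed over genes asked whether methylation moved UVB damage at whole genes. Transfer RNA genes lay below other genes in methylated DNA, with a median log2 ratio of -0.17 and 22.7% of 273 genes positive. Their median was -0.18 in UVB replicate 1, -0.15 in replicate 2 and -1.3e-04 in UVC, and over both UVB pairs it stayed between -0.11 and -0.21 in every alternative. Pooled over these genes, reads against other genes gave -0.17 ± 0.02 (bootstrap SE) in UVB replicate 1, -0.16 ± 0.02 in replicate 2 and -0.08 ± 0.03 in UVC. The 11 histone genes had a median of -0.07, which lay between -0.0061 and -0.13 without 1 library, and HHT1, a histone H3 gene on chromosome II 256331 to 256741, had -0.42 (SE 0.09), the 1 histone gene lower when adjusted over the list alone. The 20 flocculin and cell wall genes had a median of 0.04, which was -0.02 without the unmethylated library of replicate 2. In camera, adjusted p = 1.8e-13 for transfer RNA genes, 0.0163 for histones and 0.00687 for flocculins with the preset correlation, and with an estimated correlation adjusted p = 0.379 for each. In fry, which asks whether a list moves one way, adjusted p = 0.531 for transfer RNA genes and for histones and 0.671 for flocculins, while its test for change in either direction gave adjusted p = 0.0401 for histones and for snoRNA genes.

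The other lists did not pass camera. Medians were 0.03 for 7 reporter genes of UV mutagenesis (CAN1, LYS2 and others, adjusted p = 0.525), 0.03 for 30 DNA repair genes (adjusted p = 0.217), 0.0097 for 19 glycolytic genes (adjusted p = 0.499), -0.02 for 132 cytosolic ribosomal protein genes (adjusted p = 0.217), 0.0054 for 24 PAU genes (adjusted p = 0.753), -0.0064 for 12 rRNA genes (adjusted p = 0.753) and 0.01 for 76 snoRNA genes (adjusted p = 0.286). The reporter, glycolytic, PAU, rRNA and snoRNA medians changed sign when single libraries were left out. The DNA repair median then lay between 0.01 and 0.03, and the ribosomal protein median between -0.0083 and -0.03. HIS3 and LEU2, the 2 tested genes that BY4741 lacks in part or whole, had a median of -0.49 (adjusted p = 0.0659) and LEU2 had only 13 against 21 reads in replicate 1 and 0 against 1 in replicate 2. Their median was 0.92 without the unmethylated and -3.28 without the methylated library of replicate 1. They passed fry only with the block (adjusted p = 0.041).

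Of 6427 genes, edgeR called 0, with 199 at an unadjusted p under 0.05, and DESeq2 called 0. With the replicate number as a block 11 passed, named here after their values were seen. Higher in methylated DNA were the 5S rRNA genes RDN5-2 (0.40) and RDN5-1 (0.26), YLR154C-H (0.40), which overlaps RDN5-2, and the cell wall genes FLO11 and DAN4 (0.17 each). Lower were the transfer RNA genes YNCM0029C (-1.04) and EMT1 (-0.72), SIP18 (-0.57), HHT1 (-0.42) and the rRNA genes RDN58-2 (-0.24) and RDN58-1 (-0.23). The largest was YNCM0029C on chromosome XIII 586636 to 586709, with 62 against 131 reads in replicate 1 and a blocked adjusted p = 0.00151 in edgeR. In the edgeR fit without the block, YNCM0029C and HHT1 each had adjusted p = 0.997, so the count of 0 does not exclude changes of these sizes. Without the unmethylated library of replicate 1, 7 genes passed without the block, all higher. YNCM0029C was also the 1 transfer RNA gene lower when adjusted over the list alone.

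Single dipyrimidine positions were compared where at least 100 reads lay over the UVB libraries, which left mostly the tandem ribosomal DNA. In 9402 such sites, 339 rose and 644 fell in methylated DNA, and 946 of these lay in the rDNA. The site that rose most was chromosome XII 461516 to 461517 (plus strand), within the 25S rRNA gene RDN25-2, 37.4-fold higher (log2 5.22, SE 0.61, adjusted p = 7.8e-13), with 159 against 6 and 97 against 0 reads in the UVB pairs and 57 against 4 in UVC. Next were 452379 (34.0-fold) and 452381 (18.2-fold) within RDN25-1, 461517 (21.4-fold) within RDN25-2, and 458942 on the minus strand between ETS1-1 and RDN5-1 (15.9-fold). Of these, 452379 is the same position as 461516 in the other rDNA copy, 461517 overlaps 461516 and 452381 adjoins 452379. These sites in the 25S genes therefore mark 1 place in the rDNA. The site that fell most was 454456 within RDN25-1, 37.5-fold lower (log2 -5.23, SE 0.58, adjusted p = 1.6e-13), with 3 against 204 and 4 against 59 reads in UVB but 49 against 16 in UVC. Next were 463593 (33.2-fold) and 463730 (29.8-fold) within RDN25-2, 467791 (27.8-fold) between ETS1-2 and RDN5-2, and 459660 (27.5-fold) between ETS1-1 and RDN5-1. These 10 sites moved the same way in both UVB pairs, and their adjusted p-values ran from 9.5e-14 to 7.7e-09.

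Of the 328 rDNA sites that rose, 75.0% were followed by a purine, against 41.9% of the 618 that fell and 44.3% of all 8632 tested. A purine lay directly 5′ of 58.8% of the sites that rose, 23.3% of those that fell and 43.1% of all tested. In UVC, 86.3% of the sites that rose and 59.4% of those that fell had a ratio above 0, as did 66.1% of all tested rDNA sites. Both annotated rDNA copies lie 9137 bases apart, and all 900 changed sites with a tested counterpart in the other copy moved as it did, so a pair of copies is 1 measurement. With the block 2188 sites passed, all 983 among them, and without the methylated or the unmethylated library of replicate 1 the count was 408 or 462. With reads of mapping quality of at least 10, which removes most rDNA reads, 436 sites were tested and 11 passed.

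**Figure D4:**
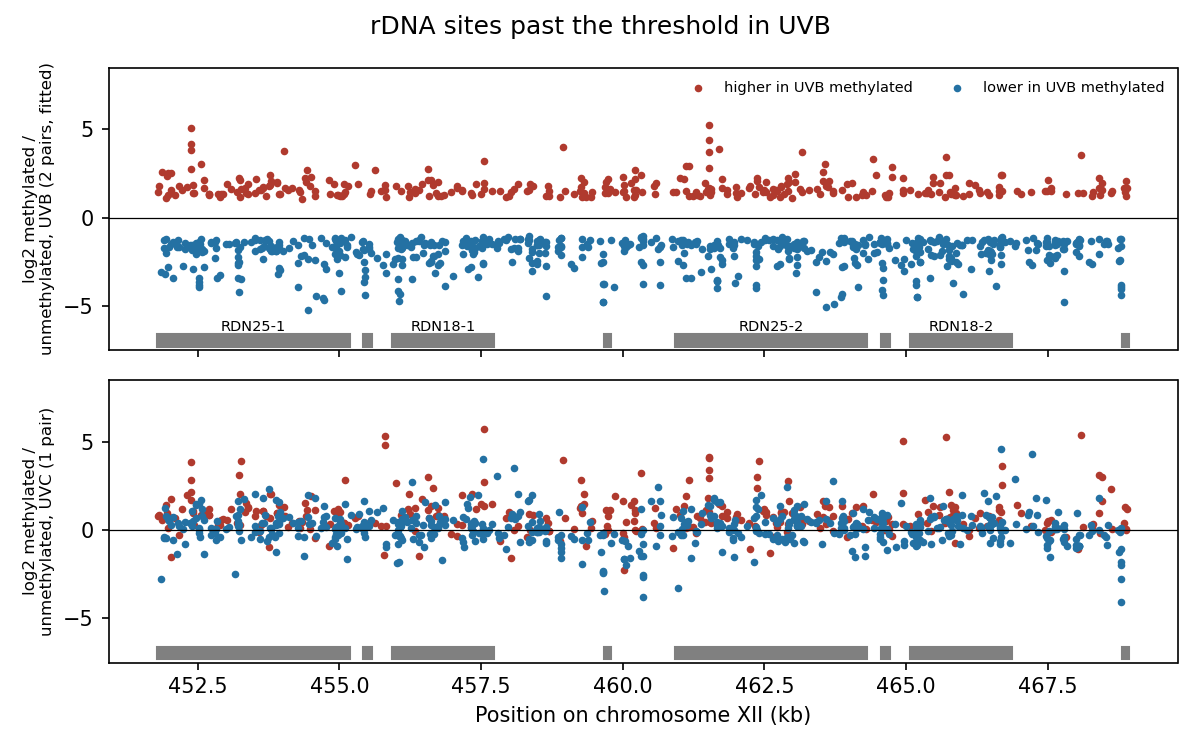
Log2 ratio of methylated to unmethylated reads (vertical axis) at rDNA sites past the threshold in UVB, by position on chromosome XII (kb), fitted over both UVB pairs (top) and in the UVC pair (bottom), with rRNA genes as grey bars. The largest UVB values are 5.22 and -5.23, both within 25S rRNA genes.

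The last comparison set UVC beside UVB. UVC libraries held more TT, at 49.4% and 50.2% of dipyrimidine reads against 43.9% to 45.4% in the 4 UVB libraries, and less CC, at 11.1% and 11.3% against 13.0% to 14.6%, differences that were not tested. Without UV the experiments differed the same way. The unirradiated library of the UVC experiment held 44.0% TT and 12.8% CC. Those of UVB replicates 1 and 2 held 41.5% and 41.1% TT, and 14.0% and 14.3% CC. With methylation as a covariate, 23 of the 64 contexts passed in edgeR, 8 higher and 15 lower in UVC. The 5 contexts that rose most, all isolated dipyrimidines, were RRR-YY-RRR (0.38, SE 0.11, adjusted p = 0.0146), RRR-YY-RYY (0.33), YRR-YY-RRR (0.26), RYR-YY-RRR (0.21) and RYR-YY-RRY (0.18). Of the 5 that fell most, 4 have pyrimidines on both sides, YRY-YY-YYR (by 0.26, SE 0.05, adjusted p = 0.00177), RYY-YY-YYR (by 0.25), YRY-YY-YYY (by 0.23) and RYY-YY-YRY (by 0.22), and YYR-YY-YYR fell by 0.22. Within the second sequencing run 13 passed, 5 higher and 8 lower, all among the 23, and without the methylated library of UVB replicate 1 the count was 15. Scaled by library size 21 passed, 10 higher and 11 lower.

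Whether methylation acted differently under UVC was tested as an interaction. Over the 64 contexts edgeR called 0, with 2 at an unadjusted p under 0.05 and a smallest adjusted p = 0.791, and DESeq2 called 0. Simulated differences of 0.2 and 0.4 were not recovered, so differences of this size were not detectable here. Over single sites, 329 of 9402 passed, 310 with a higher methylated over unmethylated ratio in UVC and 19 with a lower one. Among the sites named for their fall in UVB, a choice that favours a difference, 454456 in RDN25-1 differed by 7.21 on the log2 scale (SE 0.92, adjusted p = 4.7e-11), 463593, the same position in the other rDNA copy, by 6.67, 463730 by 4.73 and 467791 by 4.38. The other one, 459660, did not pass (2.35, adjusted p = 0.425). With the block 788 sites passed. The UVC arm has 1 library per state and other barcodes, so its spread is taken from UVB. All tested rDNA sites together had a median UVC log2 ratio of 0.24. The rDNA took 6.65% of reads in the methylated and 5.63% in the unmethylated UVC library. In UVB it took 6.78% and 6.84% in replicate 1, and 5.52% and 5.53% in replicate 2. Such an offset over the whole rDNA adds to the interaction at each site there, which favours higher ratios in UVC.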

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

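Of the tests in this part, those of a methylated CpG as the whole cause, of library-to-library differences, of the adaptor barcode, of sequence around the rDNA sites that rose and random draws by rDNA copy, of both explanations for AT and AC, and the interaction over single sites were chosen only after the result was seen.

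Several values differed between the UVC and UVB experiments, which also differ in barcode. The methylated over unmethylated ratio of single sites differed at 329 sites, or at 197 when scaled on the sites themselves, in a fit that takes the spread of the single UVC pair from UVB. Among these, chosen for their UVB fall, were chromosome XII 454456 (7.21 on the log2 scale), 463593 (6.67), 463730 (4.73) and 467791 (4.38), all on the plus strand, of which 454456 and 463593 are 1 position in both rDNA copies. In the dipyrimidine shares, the log2 ratio of UVC had the opposite sign to both UVB pairs for TT (0.0234), TC (-0.0456) and TC over CT (-0.0306), and these differences were not tested. The TT contrast depends on the denominator. As a share of all lesion reads, TT was lower with methylation in UVC and in both UVB pairs.

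In UVB methylated DNA, pyrimidine runs took fewer reads and isolated dipyrimidines more, in both pairs. A methylated CpG cytosine at the 3′ base of the dimer is argued against as the whole cause, since before 2 pyrimidines, where no such CpG can lie, a 5′ purine still raised the ratio by 0.28 in replicate 1 and 0.12 in replicate 2, with -0.10 in UVC. Background reads as seen in unmethylated DNA are argued against too. Subtracting the unirradiated library, which was not methylated, multiplied the log2 ratio of isolated dipyrimidines by 1.21 in replicate 1 and 1.18 in replicate 2. Background particular to methylated DNA was not measured, since no unirradiated library was methylated, and it stays open. Library-to-library differences stay open: at the bases 5′ of the dimer the unmethylated UVB libraries, of equal state and barcode but different runs, differed by 0.18, above the 0.14 between states in replicate 2 but below the 0.31 in replicate 1, and the pairs correlate at 0.95 across contexts. An effect of methylation on UVB dimers away from CpG and an effect of the barcode also stay open, and either may contribute. They cannot be told apart, since barcode A3 marks methylation in both UVB pairs. The larger shift was that of replicate 1, whose methylation reaction used less enzyme per amount of DNA and a shorter incubation. How far the DNA was methylated was not measured here. Isolated dipyrimidines differed more between the unmethylated UVB libraries (13.9% and 15.9% of reads) than between the methylated ones (17.0% and 17.7%). In UVC, with other barcodes, the log2 ratio of isolated dipyrimidines was 0.0067 and that of 3 pyrimidines 5′ was -0.01. A barcode effect and a methylation effect limited to UVB would both allow this.

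At single rDNA sites, methylated UVB libraries differed from unmethylated ones by up to 37.5-fold. Of the changed sites only 53.4% were followed by a purine, which argues against a methylated CpG at the 3′ base as the whole cause. By direction, it was 75.0% of risen and 41.9% of fallen sites, against 44.3% of all tested rDNA sites. For risen sites a part of such a CpG in the cause therefore stays open. The barcode stays open, since only 1 UVC pair carries other barcodes; there the median ratio of risen sites lay 0.56 (SE over copies 0.05, without spread between libraries) above that of all tested rDNA sites, and that of fallen sites -0.10 (SE 0.04) from it. For fallen sites, barcode and a methylation effect limited to UVB cannot be told apart, since both leave UVC near the other sites. Purine and pyrimidine sequence 4 to 15 bases away is argued against for fallen sites, whose largest difference in purine share was 5.88 points against 8.18 for the 95th percentile of random draws by copy (SD 1.22), but may add to the risen ones, with 14.8 points against 11.5. This leaves out the bases beside the dimer. Directly 5′, 23.3% of fallen sites had a purine, against 43.1% of all tested and 58.8% of risen ones.

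Reads outside dipyrimidines also rose at AT and AC after irradiation. AT took 21.8% ± 2.16 of these reads in irradiated libraries (SD, n = 6) and 13.2% ± 0.687 in unirradiated ones (n = 3), and AC 8.74% ± 0.966 against 6.99% ± 0.144, each above every unirradiated library in 6 of 6 (exact two-sided permutation p = 0.0238, the smallest possible). Neither comparison was planned, and these p-values were not adjusted. TA took 9.46% in irradiated and 10.5% in unirradiated libraries (p = 0.143 in the same permutation test). A lesion position set 1 base 5′ of a dimer behind an A stays open. For this, the AT over AC excess was set against the T to C ratio of the dimer's first base. The excess ratio lay within 25% of that ratio in 3 of the 6 libraries, and reached 2.05 times it in UVC methylated DNA. That T to C ratio came from all dipyrimidine reads, not only dimers behind an A, so the mismatch cannot decide. A thymine-adenine photoproduct is argued against, since the excess at TA was at most 0.102 of that at AT. What gives the AT reads stays open.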

How the results depend on the processing

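Among these results, the 64 contexts and those of 5 bases in place of the planned contexts, the single sites of any sequence, the dinucleotide test, the TC and CC ratios, the interaction over single sites, the mapping quality minimum and the fits within a run were chosen after seeing the data. Named contexts and sites kept their direction in all 444 comparisons with an alternative, and in 97 of these they no longer passed. Those of the UVB comparisons were chosen for moving the same way in both pairs, which favours a kept direction. The named sites had no comparison under the mapping quality minimum, which removes most rDNA reads. Where an arm was left with 1 library, that library was assumed to vary like the others.

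Without 1 library, the difference in dipyrimidine share lay between 53.4 and 54.5 points, and without 1 unirradiated library the exact permutation p = 0.0714, the smallest that 28 splits allow. Counts without 1 library ran from 0 to 0 for the 64 contexts, 0 to 262 for contexts of 5 bases on each side, 0 to 7 for genes, 408 to 682 for single sites and 15 to 23 for UVC against UVB. With the replicate number as a block, counts were 0 for the 64 contexts, 226 for those of 5 bases, 11 for genes, 2188 for sites, 2 for dinucleotides and 788 for the interaction over sites. The block also changed the fry test of HIS3 and LEU2 and no other fry call for one direction, it was not run for UVC against UVB or in camera, and the interaction over the 64 contexts stayed at 0 in edgeR (6 at an unadjusted p under 0.05) and in DESeq2 without the block. DESeq2 called 21 of the 64 contexts, 205 of those of 5 bases, 1 dinucleotide and 210 sites in the interaction. Subtracting the unirradiated library left 4 of the 64 contexts, and it called 1 dinucleotide where the main fit called 0. Including the mitochondrial genome left 0 of the 64 in edgeR, with 19 at an unadjusted p under 0.05 and a smallest adjusted p = 0.0573. Scaling on the sites themselves left 197 in the interaction, a mapping quality minimum left 11 of 436 tested sites, and the second run alone left 13 contexts of UVC against UVB with fewer libraries. Over TT reads the log2 ratio of TC was 0.0621 in UVB and -0.0689 in UVC, and that of CC 0.17 in UVB and -0.0031 in UVC. Over all lesion reads TC was -0.0864 and CC -0.0206 in UVC, so the sign of CC in UVC turned under both. The sign of TT in UVC also turned over all lesion reads, to that of both UVB pairs. The cause of these changes was not tested.

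The other 73 summary values kept their side of the threshold or stayed within 1.5 times. The TCG and CCG ratios planned in advance, with their alternative denominators, background, rDNA, mitochondrial and high-count settings, were not run because no genome sequence was used.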

Other observations

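In this part, the test of facing strands and that of transfer RNA genes without the T-loop TC were chosen only after the result was seen.

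Within transfer RNA genes the lower reads in UVB methylated DNA were not spread evenly. Aligned at their 3′ ends, on the gene strand, dipyrimidines ending at bases 9 and 10 from the end had ratios of -1.56 and -1.58 in UVB replicate 1 and -1.68 and -1.65 in replicate 2, with 1.02 and 0.13 in UVC. Those ending at bases 26 and 28 had 1.07 and 1.16 in replicate 1 and 0.59 and 0.84 in replicate 2, with 0.16 and 1.65 in UVC, and these bases were chosen after their values were seen. The T-loop, a conserved part of transfer RNA, was chosen before its values were seen. On the strand opposite the T-loop the methylated over unmethylated ratio, relative to the other sites of these genes, was 0.57 ± 0.12 (bootstrap SE) in UVB replicate 1 and 0.36 ± 0.14 in replicate 2, and 0.01 ± 0.20 in UVC. The unmethylated UVB libraries differed there by -0.43 ± 0.14. At the TT of the T-loop itself the values were 0.09 ± 0.11, -0.48 ± 0.16 and, in UVC, -0.57 ± 0.20.

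A candidate explanation for the lower reads over transfer RNA genes is their purine and pyrimidine context, but the 64 contexts predicted medians of 0.09 and 0.04 in the UVB pairs where -0.19 and -0.15 were observed, scaled by the sum of gene reads in place of TMM. The ratio of predicted to observed was at most -0.27, so context gives the wrong sign. Another candidate, lesions at the TC of the T-loop, which is followed by a purine, can account for little. These sites held 3.32% and 3.82% of the unmethylated reads over transfer RNA genes in the UVB pairs, so their removal could hardly move the ratio. Without these sites the pooled ratio of transfer RNA genes to other genes was as low, at -0.18 ± 0.02 and -0.16 ± 0.02 in the UVB pairs, and it was -0.08 ± 0.03 in UVC. The ratio at the sites, relative to others in these genes, was 0.23 ± 0.08 in UVB replicate 1, 0.0451 ± 0.11 in replicate 2 and 0.04 ± 0.16 in UVC. The limit on this ratio that was set beforehand for arguing against these sites was met in replicate 2 only.

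Sequence of the read away from the lesion, as library construction might leave it, was tested as a candidate cause of the context pattern. With the contexts of 5 bases on each side taken out, the mean size of the purine effect at bases 6 to 15 was 0.0095 in UVB replicate 1 and 0.0136 in replicate 2. The former is under the limit of 0.01 that would argue against it and the latter is not, which leaves it open. UVC, where isolated dipyrimidines did not differ in the same way, had 0.0110. The larger UVB mean lies in the pair with the weaker pattern. These means pool both sides of the dimer. At base 6 on the 5′ side alone, the values were 0.0595 in UVB replicate 1, 0.0269 in replicate 2 and 0.0317 in UVC. There the largest lies in the pair with the stronger pattern, so the values point both ways, and no spread was measured.

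Where dipyrimidines on opposite strands face each other over a central pyrimidine-purine step, as at a CpG, a methylated CpG changing UVB lesions on both strands would make reads on both strands change together in pairs that hold 1 UVB methylated library. By this measure the UVB methylated libraries ranked 2 of the 15 choices of 2 among the 6 irradiated libraries, and the UVC pair ranked 1, which leaves it open.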
